A study of Homo sapiens with 12 samples.

How the data were processed

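RNA immunoprecipitation followed by sequencing was performed on MDA-MB-231 cells, an established triple-negative breast cancer line. There were 12 libraries in 4 groups of 3. The parental cells (Sens) and a derivative with acquired resistance to BET inhibitors, compounds that block bromodomain and extra-terminal proteins (Res), were each precipitated with an antibody against the RNA-binding protein IGF2BP2 or with normal rabbit IgG as the background control. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures. The p-values therefore measure a spread between these libraries that may be technical and that the main fit pooled over circRNAs.

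The deposited values are raw counts per circRNA and per ERCC spike-in transcript, whole numbers that differ in total between libraries. The deposited table holds 6384 circRNA rows with circBase-style identifiers and 57 ERCC rows, and no linear transcripts. Per the labels' protocols, spike-in RNA was mixed into equal amounts of purified RNA before library preparation, and the authors scaled their data to it with RUVSeq. The deposited counts do not carry that scaling. The genome build listed in the submitters' processing notes is GRCh37. The aligner, the circRNA caller and the rule for counting a read were not given in the sources used here, so whether only back-splice reads were counted is not known. RUVSeq was not installed, and scaling to spike-in totals was used in its place as an alternative.

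ERCC rows name no gene and were left out of library sizes and tests. They took between 7.51% and 97.9% of all counts in a library. circRNA counts ranged from 1960 to 8662 per library, and an undetected circRNA has an upper limit of 3 counts. That limit is between 0.0346% and 0.153% of a library's circRNA counts. A fold against a group with 0 counts was computed against 3 counts over the group and is written as "at least". Where a group held 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval. Limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

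Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors and the quasi-likelihood test, with all 12 libraries in 1 fit and 1 coefficient per group. The prior degrees of freedom of that fit were infinite, so a circRNA's own replicates had no weight in its estimate of spread. Without Res IgG replicate 2 they were 6.06, and calls between the RIP groups went from 31 to 8. circRNAs with at least 2 counts in at least 3 libraries were kept, which left 1307. Benjamini-Hochberg adjusted p-values under 0.05 were called. The comparisons were RIP against IgG in each line, the difference of those enrichments between lines (an interaction), and Res against Sens within each antibody. The submitters' delta enrichment was computed as RIP minus IgG in RPM with the circRNA counts of a library as the denominator, Res minus Sens. This departed from the plan, which had named the counts in the file as the denominator, and the file also holds the ERCC rows. Library totals and numbers of circRNAs detected were compared with two-sided exact permutation tests, for which the smallest p that 3 against 3 libraries allow is 0.1. CPM values use TMM effective library sizes.

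The test was run on simulated counts first. Each of the 1307 circRNAs was given its mean pooled over all 12 libraries, alike in every group. Then 50 were changed at each size in Sens RIP only. The Sens enrichment test recovered 8% of 4-fold, 68% of 8-fold and 96% of 16-fold increases. It also recovered 18% of decreases to 0.125 of the level. It called 0.632% of 1107 unchanged circRNAs. Estimates were shifted down, with a median log2 fold change of -0.518 for the unchanged circRNAs. The medians were 1.40, 2.44 and 3.57 for the 3 sizes of increase and -3.40 for the decrease. The enrichment change between lines was recovered for 0%, 18%, 36% and 8% of the same sets. In 20 simulations with no change, at most 1 circRNA was called in any comparison.

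Before the data were examined, the tests, the rule for named circRNAs and the alternatives were fixed. The rule took circRNAs past the threshold whose groups did not overlap, ordered by p, with 10 per direction. For the interaction it compared RIP minus IgG differences in log2 CPM, taken between libraries of the same replicate number. That pairing by number was used for naming only, not in the main fit. The files do not pair circRNA identifiers with host genes, and 0 of the identifiers matched the gene table used here, so at most 2 identifiers per direction are printed in each comparison and no gene names are given. Lists by host gene, counts summed by host gene and circRNAs of single host genes were not analysed here for that reason. Alternatives were scaling by column totals, by spike-in totals or not at all, DESeq2 1.42.0, limma-voom (limma 3.58.1), other count filters, the replicate number as a block, a fit of only the libraries compared, and leaving out each library. Summing or dividing the IgG counts of a line, counting a pair of Sens RIP or Sens IgG libraries as 1 and further denominators for the delta were added after seeing the data.

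Replicates were compared by chi-square tests with simulated p-values at 6 minimum counts per pair. Of the 12 pairs within groups, Sens RIP replicates 2 and 3 differed at 4 of the 6 minimums and not at 10 or 20 counts, Sens IgG replicates 1 and 3 at 4 and not at 20 or 30, and the others at 5 or 6. Because the outcome depended on the minimum, all were kept as separate libraries, and counting either of the first pairs as 1 was added as an alternative. No pair was identical.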

Results

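RNA bound to IGF2BP2, an RNA-binding protein that acts on the stability and translation of its targets, was profiled in parental (Sens) and BET inhibitor-resistant (Res) MDA-MB-231 cells. The measured RNAs were circular RNAs (circRNAs), closed transcripts formed by back-splicing. There were 3 libraries for each combination of line and antibody, 12 in all. Values after ± are SDs over n = 3 libraries unless a standard error (SE) is named. circRNA counts were low, at 1960 to 2989 per library in Sens IgG, 4448 to 5561 in Sens RIP, 3860 to 6036 in Res IgG and 5179 to 8662 in Res RIP.

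Relative to the spike-in, circRNA counts were higher with the IGF2BP2 antibody than with IgG. Because the spike-in was mixed into equal amounts of purified RNA, per the labels, this scale gives circRNA per amount of RNA put in, not the amount precipitated. Per 1000 ERCC counts, there were 22.0 ± 0.267 circRNA counts in Sens IgG and 7582 ± 724 in Sens RIP, a ratio of 344. The values were 68.2 ± 1.73 in Res IgG and 10688 ± 2204 in Res RIP, a ratio of 157. Between lines, Res exceeded Sens 3.10-fold in IgG and 1.41-fold in the RIP. The groups did not overlap in the first 3 of these comparisons (exact permutation p = 0.1 each, the smallest possible, and 0.145 after adjustment over 16 comparisons of library measures). They overlapped in the RIP (exact permutation p = 0.2, adjusted 0.213). ERCC transcripts took 97.8% ± 0.0255 of all counts in Sens IgG, 93.6% ± 0.151 in Res IgG, 11.7% ± 0.948 in Sens RIP and 8.79% ± 1.84 in Res RIP. The number of circRNAs detected was 427 ± 18.0 in Sens IgG, 1727 ± 163 in Sens RIP, 1095 ± 50.9 in Res IgG and 2197 ± 433 in Res RIP. With each library thinned to 1960 circRNA counts the numbers were 411 ± 4.04, 920 ± 17.5, 828 ± 16.7 and 1021 ± 34.8, and the RIP to IgG ratio went from 4.04 to 2.24 in Sens and from 2.01 to 1.23 in Res.

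**Figure D1:**
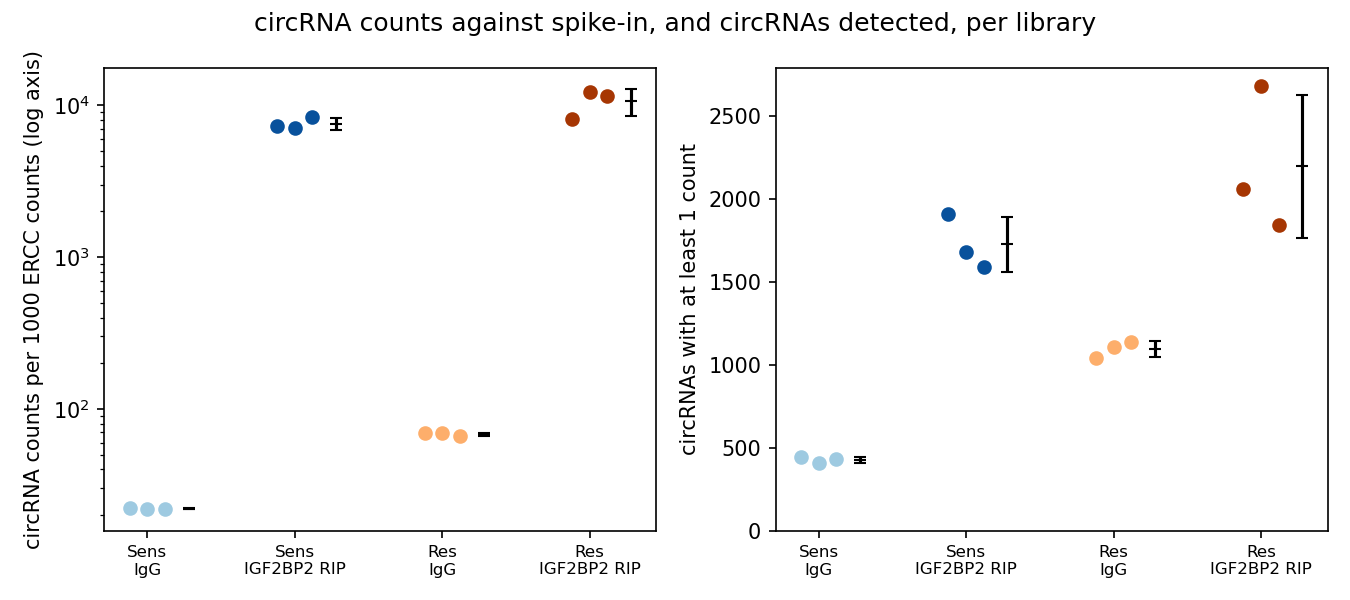
The left panel plots circRNA counts per 1000 ERCC counts on a log axis and the right panel circRNAs with at least 1 count, by group. Points are libraries and bars are the mean ± SD of 3. Sens IgG lies near 22.0 and Sens RIP near 7582.

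The first question was which circRNAs associated with IGF2BP2 in parental cells. In Sens cells, 654 of 1307 tested circRNAs differed between RIP and IgG, 520 higher and 134 lower in the RIP. DESeq2 called 235 and limma-voom 1155, and stricter filters gave 242 of 370 tested and 122 of 151. hsa_circ_0006156 had 66603 ± 9419 CPM in the RIP and 1421 ± 425 in IgG, 46.9-fold higher (log2 fold change 5.53, SE 0.26, adjusted p = 2.1e-97). hsa_circ_0021570 was 88.1-fold higher (log2 fold change 6.38, SE 0.35, adjusted p = 7.45e-71). Both were higher in 3 of 3 RIP libraries than in every IgG library. hsa_circ_0008053 and hsa_circ_0007951 had 0 RIP counts and 29 counts each over the IgG libraries, at least 4.33-fold and 4.37-fold lower (adjusted p = 3.88e-05 and 0.000195). Of the 520 higher circRNAs, 467 had no count in any IgG library.

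Calls in both directions depended on scaling. With spike-in totals, edgeR called 855 circRNAs higher in the Sens RIP and 0 lower, also 0 at an unadjusted p under 0.05, and the median log2 fold change of all tested circRNAs moved from 2.44 to 7.63. With column totals, 164 were higher and 269 lower, and with no scaling 250 and 191. Of the 134 lower calls, 10 were called higher with spike-in totals and 124 gave no call. Of those 124, 107 had 0 RIP counts, which leaves their direction on that scale undetermined, and the other 17 had a RIP to IgG ratio above 1. hsa_circ_0008053 and hsa_circ_0007951 are among the 107 (fitted log2 fold change -5.02 and -5.01, against -5.92 each with TMM, no bounds; adjusted p = 0.833 and 0.869). DESeq2 was not run on that scale.

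In Res cells, the same question gave 780 called circRNAs, 440 higher and 340 lower in the RIP. DESeq2 called 234 and limma-voom 891, and stricter filters gave 242 of 370 tested and 99 of 151. hsa_circ_0007883 had 365 summed RIP counts and 3 IgG counts, a ratio of 188 (95% interval 63.9 to 917; adjusted p = 1.59e-77). hsa_circ_0008494 had 30823 ± 3984 CPM in the RIP and 562 ± 392 in IgG, 54.9-fold higher (log2 fold change 5.74, SE 0.32, adjusted p = 2.59e-67). hsa_circ_0008053 was lower in the RIP, with 2 summed counts against 135 in IgG, a ratio of 43.6 (95% interval 11.8 to 364; adjusted p = 1.38e-18). hsa_circ_0001772 was 7.65-fold lower on the TMM scale (log2 fold change -2.96, SE 0.35, adjusted p = 2.68e-15). With spike-in totals the log2 fold change of hsa_circ_0001772 was 3.33 (adjusted p = 2.28e-09), the opposite direction, and that of hsa_circ_0008053 was 0.84 (adjusted p = 0.626). That scaling gave 877 higher and 0 lower, also 0 lower at an unadjusted p under 0.05, and moved the median from 0 to 6.01. Of the 340 lower calls, 38 were called higher and 302 gave no call, 226 of these with 0 RIP counts. Column totals gave 381 higher and 484 lower.

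**Figure D2:**
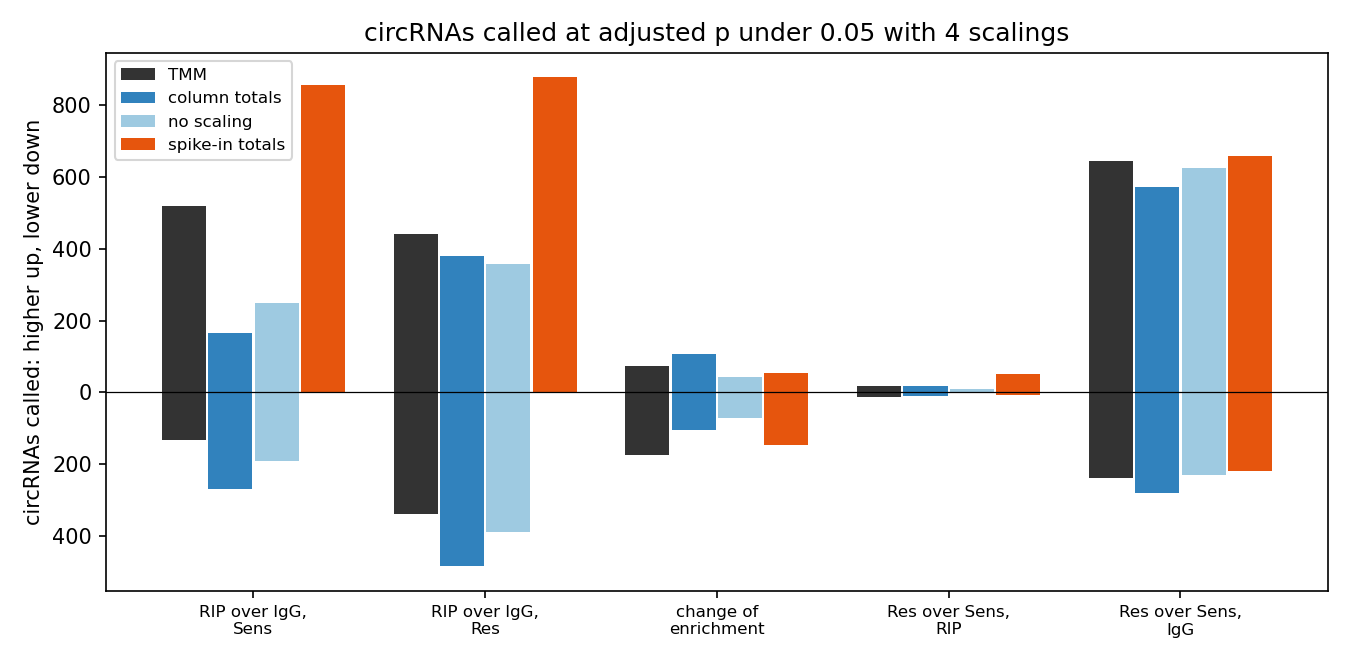
Bars give the circRNAs called at adjusted p under 0.05, higher upwards and lower downwards, in 5 comparisons with 4 scalings. With spike-in totals no circRNA was called lower in the RIP than in IgG, against 134 in Sens and 340 in Res with TMM.

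Of the circRNAs higher in the RIP, 340 were called in both lines, against 175 for independent lists of the 1307 (Fisher's exact test, p = 1.28e-88). Part of this excess is detection, since a circRNA seen mainly in IgG can hardly be called higher. Among the 608 with at least 2 counts in 3 RIP libraries, the 340 stood against 321.8 (Fisher's exact test, p = 0.000253). Among the 813 detected in the RIP of both lines, they stood against 265.7 (Fisher's exact test, p = 1.45e-27). Both sets were chosen after seeing the data. With spike-in totals, 590 of the 608 were called higher in Sens and 603 in Res, so nearly all had to be shared. The 585 shared there, against 585.1 (Fisher's exact test, p = 1), therefore decide nothing. Lower calls were shared for 11, against 34.9 of the 1307 (Fisher's exact test, p = 7.06e-08), but against 7.65 of the 149 detected in IgG of both lines (Fisher's exact test, p = 0.158), and with spike-in totals there were none to share. The lists share no libraries. Across the 1307 circRNAs, which are not independent replicates, the enrichments of the lines correlated with Pearson's r = 0.380 and Spearman's rho = 0.430. The 1307 include circRNAs with no count from either antibody in a line, where no enrichment can be measured and the fit gives about 0.

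The study asked which associations changed with resistance. On the TMM scale, the enrichment differed between lines for 248 circRNAs, 73 higher and 175 lower in Res. hsa_circ_0008285 had 115 summed RIP counts and 1 IgG count in Sens, and 166 and 106 in Res. Its RIP to IgG ratio was 247 in Sens (95% interval 43.5 to 9842) and 2.31 in Res by mean CPM (log2 change -6.17, SE 0.65, adjusted p = 4.67e-18). hsa_circ_0007444 had a ratio of 226 in Sens (95% interval 39.6 to 8994) and 2.74 in Res by mean CPM (log2 change -5.72, SE 0.71, adjusted p = 9.08e-13). hsa_circ_0007883 went the other way, from 12.4-fold in Sens to 171-fold in Res by mean CPM (log2 change 3.69, SE 0.65, adjusted p = 2.85e-06). By summed counts its Res ratio was 188 (95% interval 63.9 to 917). hsa_circ_0001165 was enriched 1.13-fold in Sens and at least 13.5-fold in Res (adjusted p = 2.23e-05). These 4 kept their direction and call on the spike-in scale, where 54 circRNAs were higher and 147 lower, all 201 among the 248. The submitters' delta, a difference and not a ratio, was -6772 RPM for hsa_circ_0008285 and -5480 for hsa_circ_0007444, but per 1000 ERCC counts it was above 0, at 26.6 and 3.44.

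Most of these changes lay in the IgG libraries. Of the 248 circRNAs, 246 were also called between the IgG groups and 8 between the RIP groups, against 168 and 5.88 for independent lists. These comparisons share libraries, so some overlap arises without a separate effect. Simulations with no change shared 0 circRNAs, but they called at most 1, so that value is no reference for the overlap. The RIP calls did not all go with the enrichment change. Of the 175 lower circRNAs, 3 were called lower in the RIP of Res and 3 higher. Of the 73 higher circRNAs, 1 was called higher and 1 lower. For the 175 lower circRNAs the median log2 change was 5.00 in IgG (quartiles 4.31 and 5.62) and -0.70 in the RIP (quartiles -1.76 and 0.02). For the 73 higher circRNAs it was -4.88 in IgG (quartiles -5.25 and -4.28) and 1.01 in the RIP (quartiles -0.04 and 2.89). Of these lists, 159 and 69 had a group at 0; with such groups set to 3 counts the medians were 2.51 in IgG and -0.46 in the RIP for the lower and -2.31 and -0.05 for the higher, and 3 of the 73 changed sign. Column totals gave 108 higher and 106 lower. The count fell to 82 without Res IgG replicate 2 and to 158 without Sens IgG replicate 3, to 130 with the IgG libraries of a line summed to 1 sample, assumed to vary like the RIP libraries, to 115 with no scaling, to 120 with DESeq2, to 116 with no filter, to 137 and 70 with stricter filters and to 2 with IgG sums divided by their modal sum, while limma-voom called 802, 225 higher and 577 lower.

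**Figure D3:**
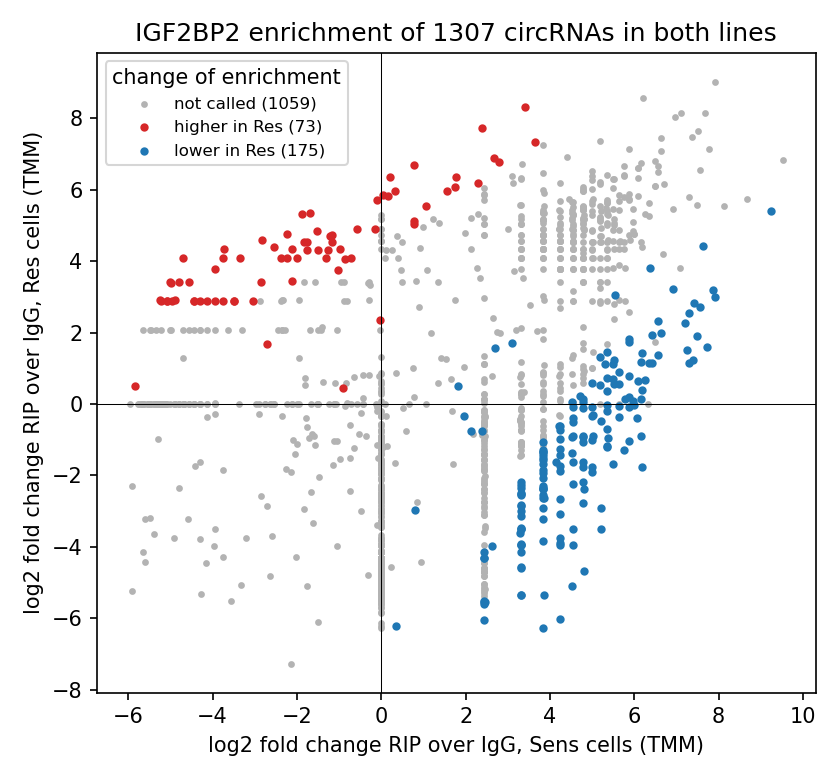
Each point is 1 of 1307 circRNAs, with the fitted log2 fold change of RIP over IgG in Sens on the x axis and in Res on the y axis, on the TMM scale. Coloured points are the 73 and 175 circRNAs whose enrichment was called higher or lower in Res; rows of points at equal values are circRNAs with a group at 0.

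Between the RIP libraries of the lines 31 circRNAs were called, 17 higher and 14 lower in Res. hsa_circ_0001573 fell from 574.7 ± 68.0 counts in Sens RIP to 6.67 ± 0.577 in Res RIP, 115-fold lower in CPM (log2 fold change -6.86, SE 0.26, adjusted p = 1.35e-148). hsa_circ_0060927 went from 53 summed counts to 1, a ratio of 73.2 (95% interval 12.6 to 2943; adjusted p = 1.68e-11). hsa_circ_0008494 was 2.90-fold higher in Res (log2 fold change 1.53, SE 0.23, adjusted p = 1.28e-08), and hsa_circ_0003611 rose from 3 summed counts to 48, a ratio of 11.6 (95% interval 3.74 to 58.2; adjusted p = 0.000397). All 4 held with spike-in totals, where 51 were higher and 7 lower; column totals gave 18 and 11, and no scaling 8 and 3. The count was 8 without Res IgG replicate 2, also with the TMM factors held. That library is outside this comparison and acted through the shared estimate of spread. The count was 15 and 19 without Sens RIP replicates 2 and 3, and 19 and 14 without Res RIP replicates 1 and 2. It rose to 39, 32 of them higher in Res, without Sens IgG replicate 3, also outside this comparison.

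The IgG libraries, the background of the assay, differed between lines for 883 circRNAs, 644 higher and 239 lower in Res. DESeq2 called 364 and limma-voom 886; stricter filters gave 259 of 370 tested and 110 of 151, and IgG sums divided by their modal sum gave 5, with 1 IgG sample per line. hsa_circ_0001573 again fell, from 393 ± 60.1 counts to 6.33 ± 3.21, 64.2-fold lower in CPM (log2 fold change -5.92, SE 0.26, adjusted p = 5.17e-109). hsa_circ_0001439 was at least 16.1-fold lower (adjusted p = 9.24e-10). hsa_circ_0008285 rose from 1 summed count to 106, a ratio of 107 (95% interval 18.7 to 4252; adjusted p = 1.7e-25), and hsa_circ_0087960 was at least 28.1-fold higher (adjusted p = 7.29e-18). Of the higher circRNAs, 608 had no count in Sens IgG, and of the lower 214 had none in Res IgG. Calls between lines in the RIP and in IgG shared 10 higher circRNAs, against 8.38 for independent lists, and 5 lower, against 2.56 (Fisher's exact test, p = 0.472 and 0.153).

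**Figure D4:**
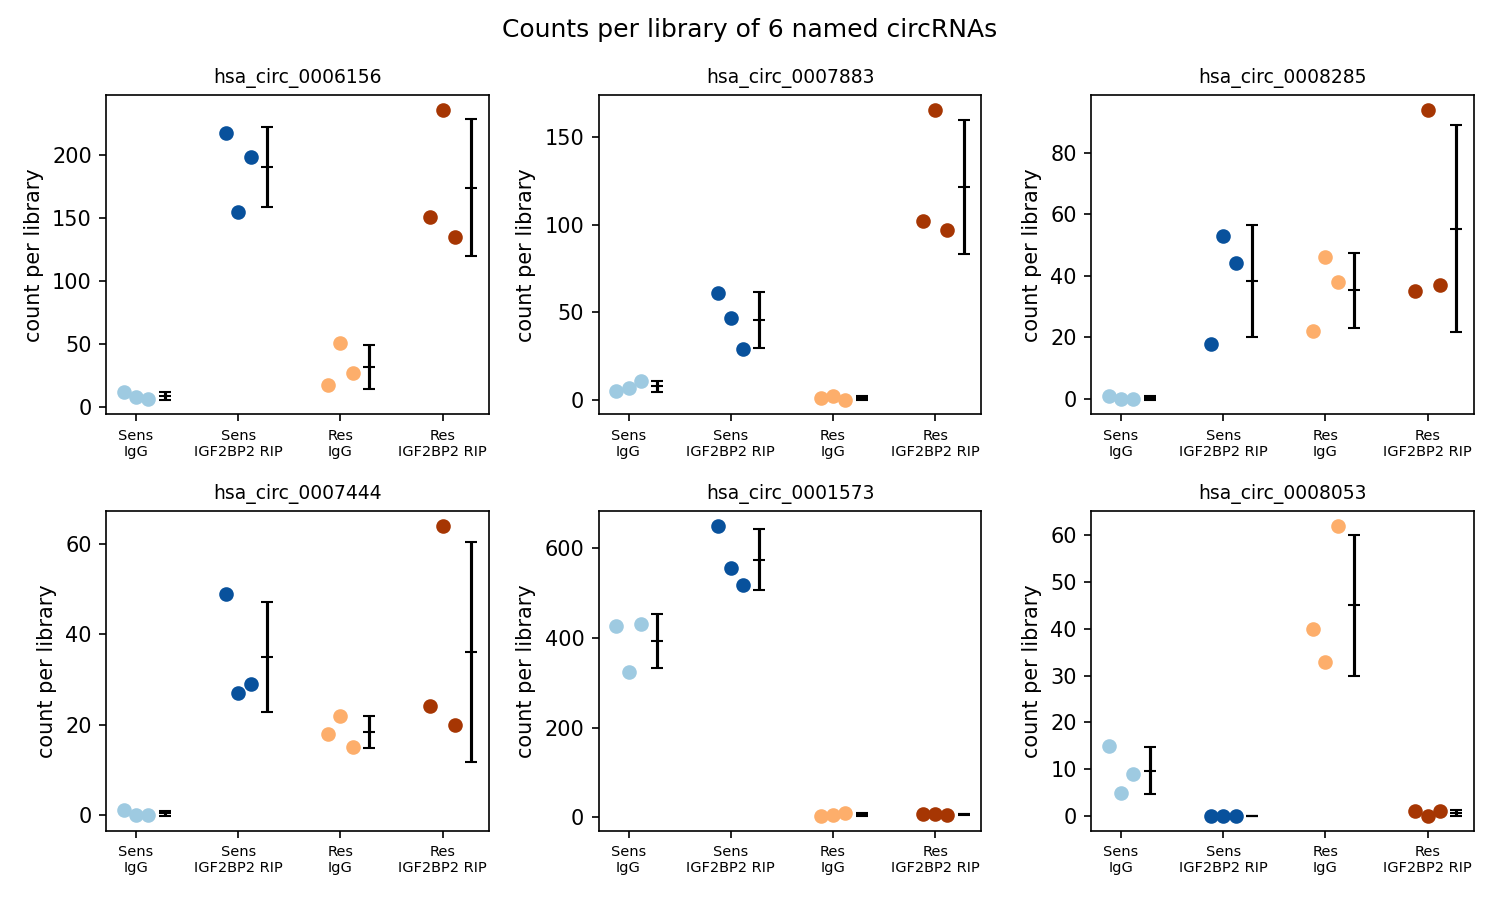
Counts per library of 6 named circRNAs by group, with the mean ± SD of 3 libraries. hsa_circ_0001573 is high in Sens and low in Res with either antibody, and hsa_circ_0008285 is near 0 in Sens IgG alone.

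**Figure D5:**
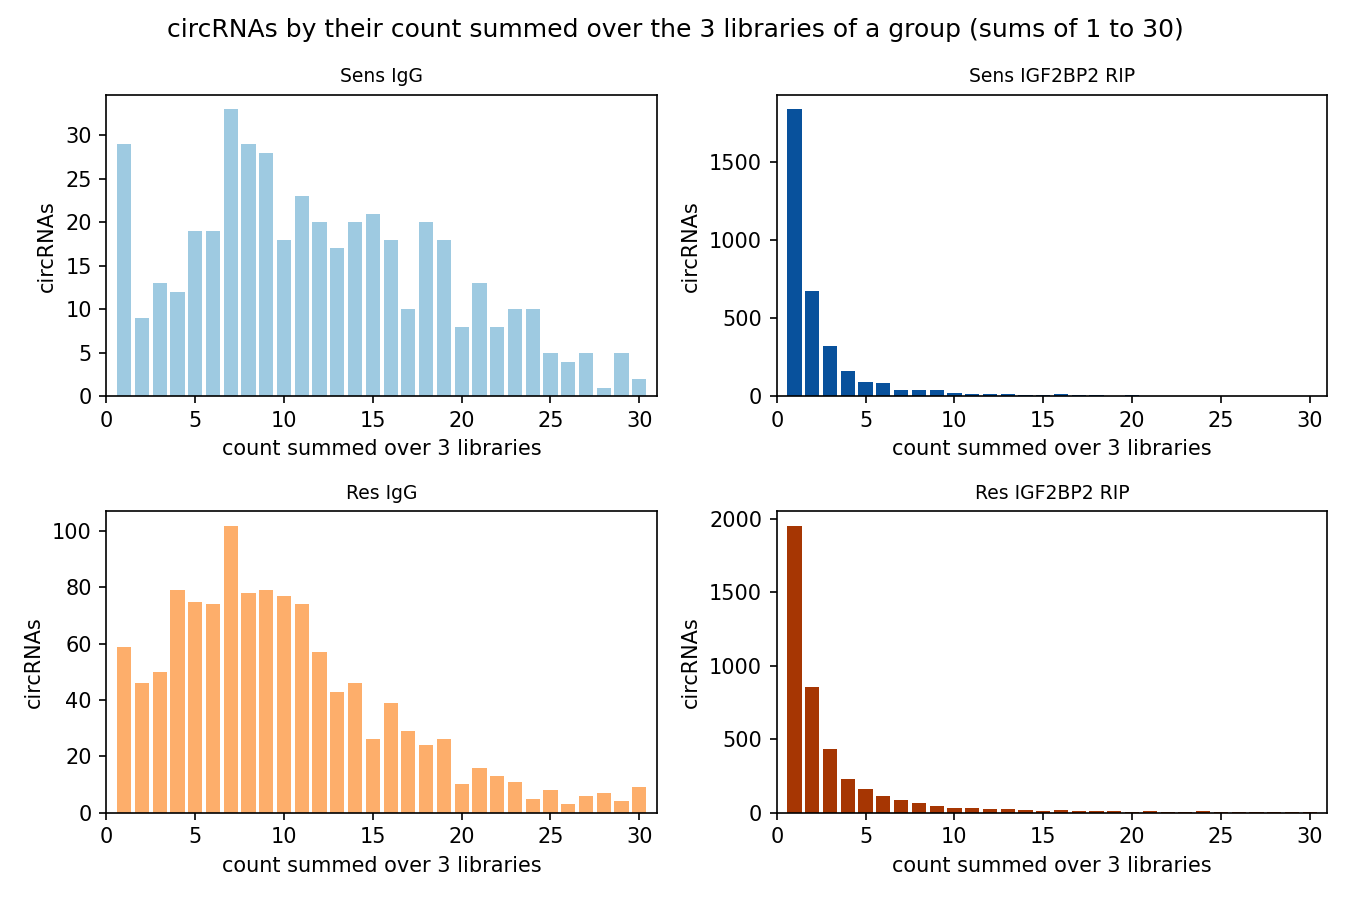
Numbers of circRNAs by count summed over the 3 libraries of a group, for sums of 1 to 30. Single counts make up 52.7% of circRNAs detected in Sens RIP and 45.7% in Res RIP, and 6.11% in Sens IgG and 4.75% in Res IgG.

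By the submitters' definition, a negative delta enrichment marks a circRNA whose association with IGF2BP2 decreased with resistance. The delta was below 0 for 765 of 1307 circRNAs (58.5%) and above 0 for 542, and 167 of the 175 circRNAs with a lower enrichment on the TMM scale were among the 765. The lowest values belonged to hsa_circ_0006156, at -14823 RPM (SE 3927), and hsa_circ_0001772, at -8344 (SE 1057). The highest belonged to hsa_circ_0001573, at 36220 (SE 6648), and hsa_circ_0007883, at 12282 (SE 1559). The delta of hsa_circ_0001573 arose from 152990 ± 11504 RPM in Sens IgG and 116627 ± 228 in Sens RIP, with 1207 ± 394 and 1063 ± 223 in Res. It turned to -98788 with all counts of the file, the denominator named in the plan, and to -870 per 1000 ERCC counts. Per 1000 ERCC counts, 495 deltas were below 0 and 812 above.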

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

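The tests of technical and biological explanations in this part were chosen after the results were seen. An exception is the number of calls over all splits of the libraries, which was set out before it was run. Sorting those splits by whole, exchanged or mixed IgG groups, and the argument from that sorting, came after the results were seen. The results flagged here are differences between the lines in the effect of the antibody. The enrichment of 248 circRNAs differed between Sens and Res by the interaction test. Among them, the fitted log2 change was 3.69 for hsa_circ_0007883, 6.16 for hsa_circ_0001165, -6.17 for hsa_circ_0008285 and -5.72 for hsa_circ_0007444. The value of hsa_circ_0001165 is no bound, since its Res IgG libraries are at 0.

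The enrichment changes followed the IgG libraries. A change of IGF2BP2 binding alone is argued against as the whole cause in both directions. The 175 lower circRNAs had a median RIP log2 change of -0.70 against an enrichment change of -5.78, and the 73 higher ones 1.01 (upper quartile 2.89) against 6.16; with groups at 0 set to 3 counts the medians were -0.46 against -2.89 and -0.05 against 2.33. A difference between the IgG pools of the lines is a candidate explanation. The 13 splits that kept or exchanged whole IgG groups and relabelled the RIP libraries each called at least 215 circRNAs. Of the 248, 125 to 180 were among them, counted without regard to direction. In 7 of the 13 splits the IgG lines were exchanged, which reverses the IgG difference. Every such split keeps the IgG groups intact, so the counts show only that the RIP labels were not needed. The 246 of the 248 that were also called between the IgG groups add little, since both tests use the same IgG libraries. Whether these IgG counts stand for few molecules stays open: dividing the IgG sums by their modal sum of 7 left 2 calls, with 1 IgG sample per line assumed to vary like the RIP libraries, but random thinning to the same totals left a median of 3.5 in 20 runs, so loss of depth alone gives as low a count. A real difference in the background RNA of the lines also stays open.

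The line labels were shuffled within each antibody in 100 splits, the real one included. Of these, 11 gave at least the real 248 calls, with 357 the highest of the others, so chance is not excluded for this count. The splits are a poor reference for chance, however. Every other split with any call kept or exchanged whole IgG groups, and so kept the real contrast between the IgG groups. The splits point to a structure of the samples. In the 85 splits that mixed the IgG lines edgeR called 0, but mixing also adds the difference between lines to the spread. The 13 splits with whole IgG groups and relabelled RIP libraries called 215 to 324, so a count of this size did not require the RIP labels, and exchanging the IgG lines alone gave the 357. The other comparisons were refitted on their own 6 libraries, where 10 splits are too few for a share under 0.05. The real split, 1 of 10 in each, gave 539 calls for Sens enrichment, 746 for Res enrichment, 24 for the RIP between lines and 873 for IgG between lines, and the highest other split gave 0 in each.

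The IgG libraries of a line detected largely the same circRNAs, with few single counts. Of 475 circRNAs detected in Sens IgG, 77.7% were in all 3 libraries and 6.11% had a summed count of 1; in Res IgG the values were 72.0% and 4.75% of 1243. Depth is argued against, since Sens RIP libraries thinned to the Sens IgG totals had 10.2% in all 3 and 60.8% single (100 thinnings). A background common to both lines stays open: 58.6% of the 186 circRNAs with a mean of at least 5 in Sens IgG were at 0 in all Res IgG libraries, and 76.3% of the 304 such circRNAs in Res IgG were at 0 in all Sens IgG libraries, but small pools drawn from a common background would give such zeros too, and 153 circRNAs were detected in both against 92.5 for independent sets. A candidate explanation is that the 3 IgG libraries of a line sampled 1 small pool of amplified molecules, in which case their spread would not be that of independent precipitations.

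hsa_circ_0001573 was high in Sens and low in Res with either antibody. Loss of IGF2BP2 binding alone is argued against by the log2 fold change of -5.92 in IgG, and its enrichment change was -0.94 (SE 0.48, adjusted p = 0.156). A contaminant added in a fixed amount relative to the spike-in of each Sens library is argued against. The count per 1000 ERCC counts was 263 times higher in Sens RIP than in Sens IgG. That ratio is not particular to hsa_circ_0001573, since all circRNA counts together were 344 times higher on this scale. A contaminant at a fixed count per library is not addressed, as mean counts were 393 in Sens IgG and 575 in Sens RIP. Scaling is argued against, as the smallest fall in the RIP over 4 scalings was 6.35 on the log2 scale (log2 fold change -6.35). A lower abundance of this circRNA in Res cells is a hypothesis that stays open, as no input libraries were analysed here.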

How the results depend on the processing

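Alternatives with summed or divided IgG counts, with a pair of Sens RIP or Sens IgG libraries counted as 1, and with a spike-in denominator for the delta were chosen after seeing the data. The file-total denominator of the delta, run here as an alternative, was the one named in the plan. Calls are given for Sens enrichment, Res enrichment, the enrichment change, the RIP between lines and IgG between lines, which had 654, 780, 248, 31 and 883. In that order DESeq2 gave 235, 234, 120, 19 and 364, with 583 to 937 adjusted p-values not given. Without a filter the counts for Sens enrichment, the change and the RIP were 380, 116 and 17. A minimum of 10 (filterByExpr, 151 tested) gave 122, 99 and 70 for the first 3 and 110 for IgG; at least 5 counts in 3 libraries (370 tested) gave 242, 242, 137 and 259. limma-voom gave 1155 for Sens enrichment, 802 for the change and 53 for the RIP. Column totals gave 433 for Sens enrichment, no scaling 115 for the change and 11 for the RIP, and spike-in totals 58 for the RIP. Summed IgG libraries gave 404 for Sens enrichment and 130 for the change; IgG sums divided by their modal sum gave 68, 67, 2 and 5 for Sens, Res, the change and IgG. These fits hold 1 IgG sample per line, assumed to vary like the RIP libraries, so IgG between lines is 1 against 1. Counting Sens RIP replicates 2 and 3 as 1 gave 640, 781, 258, 23 and 883, and Sens IgG replicates 1 and 3 as 1 gave 594, 774, 209, 21 and 879. Fewer circRNAs tested accounts for part of the lower counts under stricter filters; otherwise the cause was not tested.

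Leaving out 1 library gave 488 to 654, 631 to 785, 82 to 221, 8 to 39 and 792 to 886 calls. The replicate numbers showed no pairing of libraries. The 18 same-number pairs had correlations of deviations from -0.066 to 0.052, and 0 libraries correlated best with their own number in every other group. At these low counts, counting noise could hide a shared replicate effect, so a pairing is not excluded. With the replicate block the counts were 445, 522, 166, 17 and 737.

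With spike-in totals 2 named values reversed, hsa_circ_0008053 (0.84) and hsa_circ_0001772 (3.33) in Res enrichment. With those totals hsa_circ_0008053 and hsa_circ_0007951 lost the call in Sens enrichment, and their RIP count of 0 leaves the direction undetermined. Of the other combinations of a named test value and an alternative, 505 kept direction and call and 7 kept direction without the call, groups at 0 set to 3 counts. The delta was below 0 for 765 circRNAs, 756 to 774 without 1 replicate number, 3214 over all 6384 circRNAs, 191 of 370 under the stricter filter and 495 per 1000 ERCC counts. The delta of hsa_circ_0001573 reversed to -181 in raw counts, -136110 RPM with TMM sizes, -98788 with file totals and -870 per 1000 ERCC counts, and per 1000 ERCC counts those of hsa_circ_0008285 (26.6) and hsa_circ_0007444 (3.44) reversed. Ratios of library totals and of circRNAs detected kept their direction under each alternative run, but the RIP to IgG ratio of circRNAs detected fell from 4.04 in Sens and 2.01 in Res to 2.24 and 1.23 after thinning and to 1.74 and 1.08 at 2 or more counts, where the Res groups overlapped (exact permutation p = 0.8). Counts summed by host gene and lists by host gene were not run. Of 50 simulated 4-fold enrichment changes, 0 were recovered, with the same means in every group and only Sens RIP changed. Most changes of that kind would be missed at this depth. Among the called changes, 159 of the 175 lower and 69 of the 73 higher had a group at 0, so the rate need not hold for such circRNAs.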

Other observations

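These summaries were chosen after seeing the data. Among circRNAs seen in the RIP, the share detected in IgG was higher at higher RIP counts. Among 2504 circRNAs with 1 count summed over the 6 RIP libraries, 2.52% were detected in Sens IgG and 6.83% in Res IgG. Among 416 with 9 to 20 counts the shares were 14.7% and 30.8%, and among 57 with at least 61 counts they were 50.9% and 70.2%. Of the circRNAs detected, 153 were shared by Sens IgG and Res IgG, against 92.5 for independent sets (Fisher's exact test, p = 6.11e-12). The table lists no circRNA without a count, so the 568 with no RIP count were all seen in IgG, 22.7% in Sens and 79.8% in Res. In all, 129 of the 475 circRNAs in Sens IgG (27.2%) and 453 of the 1243 in Res IgG (36.4%) had no count in any RIP library.

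Rank correlations between replicates, which zeros shared by libraries raise, differed by antibody. Spearman's rho between libraries, across all 6384 circRNAs, which are not independent replicates, was 0.898 to 0.930 in Sens IgG and 0.873 to 0.895 in Res IgG. It was 0.271 to 0.287 in Sens RIP and 0.278 to 0.307 in Res RIP. Over circRNAs with at least 2 counts in a pair, the chi-square per degree of freedom was closer between antibodies, at 1.28 to 1.29 in Sens IgG, 1.34 to 1.35 in Sens RIP, 1.23 to 1.32 in Res IgG and 1.38 to 1.58 in Res RIP. Between the lines, summed IgG counts had a rho of 0.105 and summed RIP counts 0.139.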
